A study of Arabidopsis thaliana with 8 samples.

How the data were processed

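The values come from Affymetrix Agronomics tiling arrays hybridised with biotin-labelled RNA, 1 sample per array. Seedlings of rml1 and Columbia-0 grew for 7 days on medium with 1 mM KNO3, 100 µM NaH2PO4 and 0.5% sucrose, at 150 µmol of light per square metre and second, a photoperiod of 16 h and 20 degrees, per the labels' protocols. Per the submitters' processing notes, the authors deposited RMA values on the log2 scale, that is background-corrected, quantile-normalized and summarised per gene by that method. The version of RMA, the assignment of probes to genes and the genome build are not given in the sources used here, so no positions are printed. Array medians lay between 3.85 and 4.00, and values ran from 0.350 to 13.4. RMA can compress differences at both ends of this range, which was not tested here, and detection above background was not analysed here.

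The table held 30237 entries for 29920 loci. Suffixes on the locus codes (0 at 25387 entries, X at 4325 and higher numbers at 525) have no stated meaning, and entries of a locus were averaged. Of 208 loci with more than 1 entry, 35 had some entries called and others not when each was tested by itself, and 0 had entries called in opposite directions. The 8 values of 85 entries were identical to those of another entry, as can happen where genes share probes. Gene symbols came from a RefSeq gene table of the assembly TAIR10.1, used only for names and gene order, and 29715 entries matched it by locus code. For close relatives such as the transferases of tandem clusters, probes can respond to more than 1 gene.

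Groups were taken from the sample labels, which call the 3 shoot samples of each genotype biological replicates. The labels give no harvest time or batch. Shoots were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values of the 6 shoot arrays, genotype as the only term, two-sided, Benjamini-Hochberg adjustment over 29920 loci), and a locus was called at an adjusted p under 0.05. Error terms are SDs of arrays or standard errors of the log2 fold change, and folds are 2 to the power of that change. The fit was checked on simulated data for 29920 loci with 200 changed, of which 50 each were changed by 0.5, 1, 2 and 4 log2 units; 144 loci were called, 6 of them falsely.

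The gene lists (25, with 463 members, 450 of them measured here), the test of each comparison, the alternatives and the rule for naming genes were fixed before the data were examined. Of 463 symbols, 446 matched the gene table and the others were kept by locus. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and with fry as alternatives. With an estimated correlation 0 lists were called and 4 had an unadjusted p under 0.05, while fry called 14. Camera compares a list with all other genes, and fry tests only whether its members move.

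The rule named GSH1, the 10 largest rises and 10 largest falls among called loci with non-overlapping groups and a mean above the median in at least 1 genotype, and the most strongly changed called member of each list in each direction. It also allowed any member of the glutathione, auxin and strigolactone lists. Other list members given as examples, and the loci added in the closing part, were chosen after their values were seen. Roots have 1 array per genotype and no test. For these, the 10 largest differences in each direction among loci with at least 1 array above its median were named, with the extreme member of each list that differed by at least 1 log2 unit. Each list median was placed among 10000 random lists matched on mean expression in 20 bins. Loci of random lists were drawn independently, whereas members of a gene list can move together, so a percentile is not a test. The agreement of roots with shoots was described across loci, with an exact binomial interval that covers counting only.

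Alternatives were quantile normalization or median centring of the arrays, filters on low loci, eBayes with trend and robust options, array weights, the replicate number as a block, each array left out in turn, other thresholds, and each table entry tested by itself, which was chosen after the data were seen. Lists of sugar, clock and DNA damage genes used in the closing part were written after the main results and before their own values were examined. Some values of single genes are not reported here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.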

Results

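Gene expression was measured in Arabidopsis seedlings of the root meristemless1 (rml1) mutant and of the Columbia-0 wild type, separately in shoots and in roots, 7 days after the start of growth on vertical plates. The rml1 mutant carries a lesion in GSH1, which encodes glutamate-cysteine ligase, the first enzyme of glutathione synthesis, and its primary root stops growing soon after germination. The series title places the comparison in the study of how redox state acts on auxin and strigolactone signalling in root growth. There were 8 tiling arrays: 3 of rml1 shoots, 3 of wild type shoots, 1 of rml1 roots and 1 of wild type roots. The shoot samples of rml1 pooled 61, 65 and 108 shoots and those of the wild type 30 shoots each, while the root samples pooled 234 rml1 roots and 90 wild type roots. In each genotype the root count equals the total of the shoot counts. The roots may therefore come from the same seedlings as the shoots. The small number of arrays limits the precision of each comparison, and the root difference has no replicate error.

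The levels of organ markers separated the shoot from the root arrays. The median level of 33 nuclear photosynthesis genes lay between 12.26 and 12.43 log2 units in the 6 shoot arrays, at 7.99 in the rml1 root and at 7.49 in the wild type root. Genes of the endodermis and the Casparian strip, the barrier layer of the root, had a median of 8.18 in the wild type root, 6.03 in the rml1 root, 4.67 to 4.80 in rml1 shoots and 4.45 to 4.58 in wild type shoots. The median of 10 root hair genes was 5.75 in the rml1 root, 5.31 in the wild type root and 3.05 to 3.71 in the shoot arrays. Root meristem and stem-cell regulators were near the low end of the scale in all arrays, at 3.04 in the rml1 root, 3.35 in the wild type root and 2.57 to 2.84 in shoots. Across loci, Pearson's r between shoot replicates was 0.990 to 0.994 within a genotype and 0.967 to 0.977 between rml1 and wild type shoots. The rml1 shoot arrays correlated with the rml1 root at 0.890 to 0.895, and the wild type shoot arrays at 0.850 to 0.858.

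The first comparison asked which genes differ between rml1 and wild type shoots (n = 3 arrays each). GSH1 (AT4G23100), the mutated gene, had a mean of 8.79 ± 0.17 in rml1 and 8.25 ± 0.18 in the wild type (log2, SD), a rise of 0.54 (SE 0.13, adjusted p = 0.0243). This call was lost without any of 4 of the arrays (adjusted p 0.0727 without rml1 replicate 1, 0.0828 without rml1 replicate 3, 0.0731 without wild type replicate 2 and 0.0761 without wild type replicate 3). A point lesion leaves the transcript in place, so this level does not check the genotype labels.

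A plastid sugar phosphate translocator and both marker enzymes of the glyoxylate cycle were among the largest rises in rml1 shoots. GPT2 (AT1G61800), a plastid glucose-6-phosphate translocator, rose 119-fold (log2 6.89, SE 0.43, adjusted p = 0.00021), from 3.70 ± 0.91 to 10.59 ± 0.31. ICL (AT3G21720) and MLS (AT5G03860), isocitrate lyase and malate synthase of the glyoxylate cycle, rose 70.2-fold and 45.4-fold (log2 6.13, SE 0.18, and 5.50, SE 0.24). TH8 (AT1G69880), an h-type thioredoxin, rose 44.9-fold (SE 0.22 on the log2 scale), MYB75 (AT1G56650), an activator of anthocyanin synthesis, 28.7-fold (SE 0.23), BGLU11 (AT1G02850), a beta-glucosidase, 24.6-fold (SE 0.20) and GSTU24 (AT1G17170), a glutathione S-transferase, 23.5-fold (SE 0.34). The other members of the 10 largest rises were AT2G47780 (66.5-fold), AT1G80130 (45.2-fold) and AT1G73120 (37.1-fold). The adjusted p of these 10 genes ranged from 3.29e-05 for ICL to 0.000331 for GSTU24.

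Among the falls, AT1G66100 was 42.3-fold higher in the wild type than in rml1 (log2 -5.40, SE 0.37, adjusted p = 0.00027) and AT3G01345 was 35.3-fold higher (log2 -5.14, SE 0.15, adjusted p = 3.29e-05). PPT2 (AT3G01550), a plastid phosphoenolpyruvate translocator, was 18.2-fold higher in the wild type (SE 0.27) and BT5 (AT4G37610), a BTB and TAZ domain protein, 14.1-fold (SE 0.22), while SWEET16 (AT3G16690), a sugar transporter of the vacuole, fell by 3.81 (SE 0.28). The remaining genes of the 10 largest falls were AT1G13650 (17.5-fold), AT1G62510 (16.7-fold), AT3G15450 (16.4-fold), AT1G29720 (13.7-fold) and AT2G20670 (log2 -3.74).

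**Figure D1:**
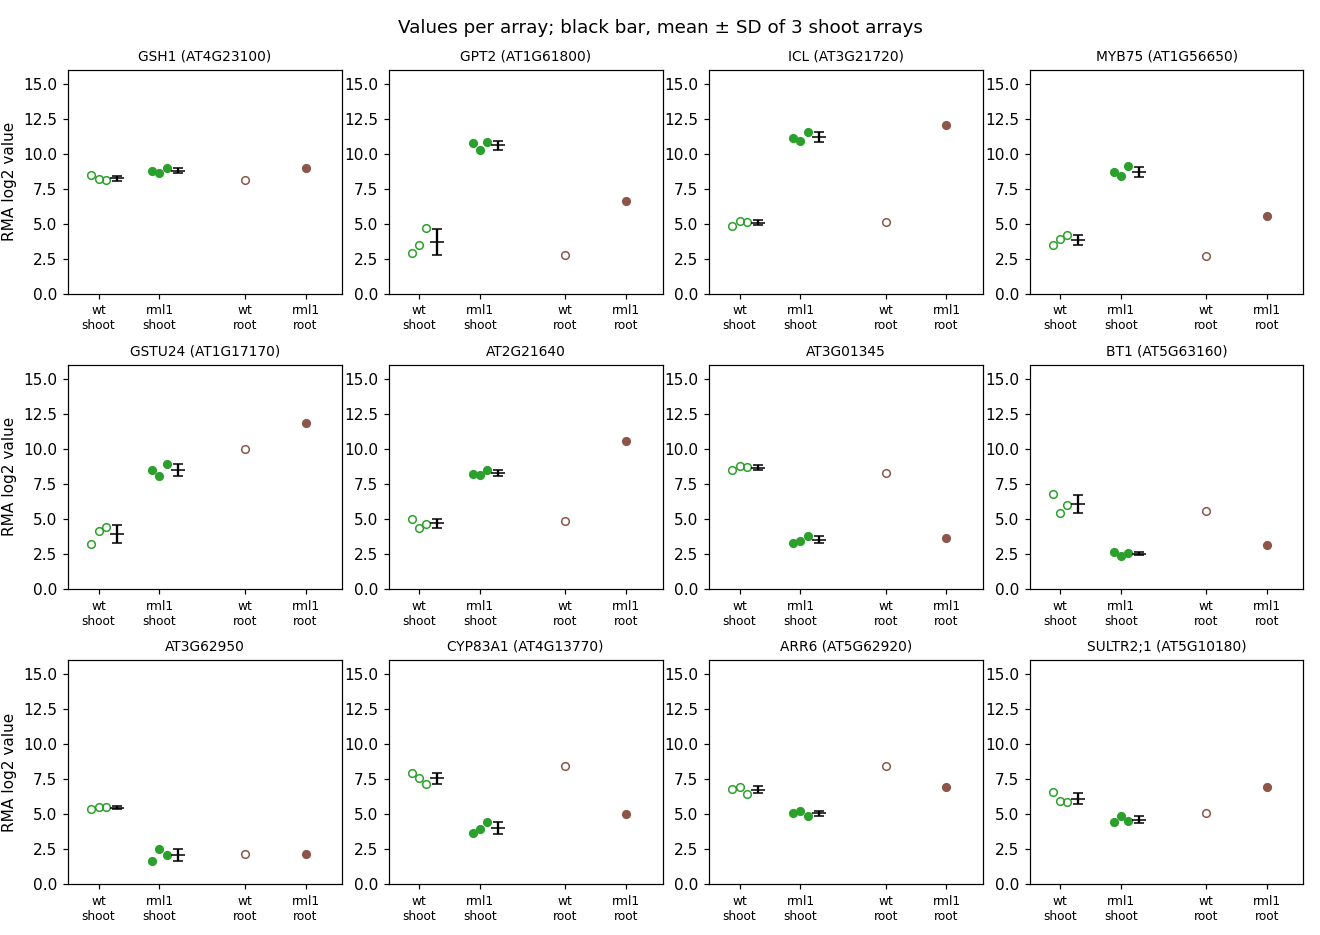
Level of 12 named genes in each of the 8 arrays (log2, 1 point per array, rml1 and wild type filled for rml1 and open for the wild type, green for shoots and brown for roots; black bars mark the mean and SD of 3 shoot arrays). GPT2, ICL, MYB75, GSTU24 and AT2G21640 lay higher in rml1 shoots, and AT3G01345, BT1, AT3G62950, CYP83A1, ARR6 and SULTR2;1 lay lower.

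Of 29920 loci, 7138 (23.9%) changed, 3970 up and 3168 down, and 1446 of them changed at least 2-fold. Without rml1 replicate 3 the number of changed loci was 4508. The 2 groups of 3 arrays did not overlap at 12595 loci (42.1%), where chance gives 10%. On simulated changes, 18% of 0.5 log2 units, 68% of 1 unit, 90% of 2 units and 100% of 4 units were recovered. The simulation called 144 loci, against 7138 here. With fewer calls the Benjamini-Hochberg adjustment asks for a smaller unadjusted p, so these shares need not hold for this comparison. Changes under 2-fold may still have been missed with 3 arrays each, and how many was not tested.

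Glutathione-linked and redox genes moved in both directions in shoots. Of 11 genes of cysteine and glutathione synthesis, 5 rose, 1 fell and 5 did not pass (8 rose and 2 fell when adjusted over the list alone). CLT3 (AT5G12170), a glutathione transporter of the plastid envelope, rose by 1.58 (SE 0.14), SERAT2;1 and SERAT2;2, serine acetyltransferases, rose by 0.83 (SE 0.12) and 0.77 (SE 0.08), GSH2, glutathione synthetase, rose by 0.63 (SE 0.09), and CLT2 fell by 0.43 (SE 0.08). The list was called up by camera (adjusted p = 0.00523), with adjusted p = 0.364 with an estimated correlation. Of 35 glutathione S-transferases, 18 rose, 6 fell and 11 did not pass (19 and 7 when adjusted over the list alone). GSTU24 led the rises, GSTF6 rose 8.43-fold (log2 3.08, SE 0.16), and GSTF14 (AT1G49860) had the largest fall (log2 -2.64, SE 0.61, adjusted p = 0.0209), a call lost without any of 4 arrays (rml1 replicate 2, 0.0657, rml1 replicate 3, 0.0761, wild type replicate 2, 0.0663, and wild type replicate 3, 0.0694). The transferase list was called up (adjusted p = 0.00205, and adjusted p = 0.227 with an estimated correlation). With only loci above the median of expression, neither list was called (adjusted p = 0.0933 for synthesis and 0.0708 for the transferases).

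The CC-type glutaredoxins, plant-specific small redox proteins, fell as a group. Of 11 members, 10 fell and 1 did not pass (10 when adjusted over the list alone). Camera gave an adjusted p = 1.26e-07, and adjusted p = 0.227 with an estimated correlation. With 1 array left out 8 to 10 fell, and 5 fell with only loci above the median of expression, a filter that drops low members. AT3G62950 had the largest fall, 10.6-fold higher in the wild type (log2 -3.40, SE 0.20), followed by GRXS13 (log2 -2.43, SE 0.42), and ROXY2, which acts in flower development, fell by 1.45 (SE 0.19). The mean of AT3G62950 in rml1, 2.06, lay below the lower quartiles of the rml1 shoot arrays (2.14 to 2.24), so its fold is uncertain. AT4G15660, AT4G15680, AT4G15690 and AT4G15700, which all fell, have neighbouring locus codes and may share probes, so these may not be separate falls. Markers of reactive oxygen and mitochondrial stress had 6 of 9 members rising and 3 not passing (6 when adjusted over the list alone; adjusted p = 0.00068, and adjusted p = 0.227 with an estimated correlation). AT2G21640, a marker of oxidative stress, rose 12.2-fold (log2 3.61, SE 0.18) and AOX1A, the alternative oxidase of mitochondria, rose by 1.79 (SE 0.16). Of 25 antioxidant and thiol-redox enzymes, 12 rose, 5 fell and 8 did not pass (12 and 6 when adjusted over the list alone), and the list was not called (adjusted p = 0.0506). It was called with array weights (adjusted p = 0.0298), without rml1 replicate 2 (0.0203), without wild type replicate 1 (0.0299) and with fry (0.0136). DHAR1, a dehydroascorbate reductase, rose by 1.22 (SE 0.10), CAT3, a catalase, rose by 1.21 (SE 0.13), and GPX1, a plastid glutathione peroxidase, fell by 1.27 (SE 0.12).

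Of 21 genes of sulfate uptake, assimilation and sulfur starvation, 3 rose, 4 fell and 14 did not pass (3 and 5 when adjusted over the list alone), and the list was not called (adjusted p = 0.484). With 1 array left out, 0 to 3 rose and 2 to 5 fell with limma, while 9 members had an unadjusted p under 0.05 with all arrays. BGLU28, a beta-glucosidase induced by sulfur deficiency, rose by 1.15 (SE 0.25, adjusted p = 0.0162), a call lost without wild type replicate 2 (adjusted p = 0.0514) or wild type replicate 3 (0.0525). SULTR2;1 (AT5G10180), a sulfate transporter of vascular tissue, fell by 1.51 (SE 0.22).

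Flavonoid and glucosinolate genes moved in opposite directions in shoots. Of 16 genes of flavonoid and anthocyanin synthesis, 14 rose and 2 did not pass (14 when adjusted over the list alone), with a median of 1.82 (camera adjusted p = 3.48e-11, and adjusted p = 0.227 with an estimated correlation). Besides MYB75, its relative MYB90 rose 12.9-fold (log2 3.69, SE 0.17), DFR, dihydroflavonol reductase, 14.8-fold (log2 3.89, SE 0.35) and CHS, chalcone synthase, by 1.63 (SE 0.16). Of 22 genes of glucosinolate synthesis, 3 rose, 12 fell and 7 did not pass (4 and 13 when adjusted over the list alone; adjusted p = 0.00466, and adjusted p = 0.586 with an estimated correlation). The falls included CYP83A1 (log2 -3.55, SE 0.26), BCAT4 (log2 -3.37, SE 0.31) and the regulators MYB29 (log2 -2.66, SE 0.28) and MYB28 (log2 -1.58, SE 0.17), all of the methionine-derived branch. MYB51, a regulator of the tryptophan-derived branch, rose by 1.08 (SE 0.10).

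Of 15 genes of nitrate uptake, assimilation and response, 1 rose, 7 fell and 7 did not pass (1 and 7 when adjusted over the list alone; adjusted p = 0.0272, adjusted p = 0.227 with an estimated correlation and 0.051 without wild type replicate 3). BT1, a BTB and TAZ domain protein, was 11.7-fold higher in the wild type (log2 -3.55, SE 0.30), BT2 fell by 1.84 (SE 0.23) and LBD39, a nitrate-responsive repressor, fell by 2.33 (SE 0.17), whereas RFNR1, a root-type ferredoxin reductase, rose by 1.85 (SE 0.14). Of 15 phosphate starvation genes, 2 rose, 1 fell and 12 did not pass (adjusted p = 0.896), and 1 to 3 rose and 1 to 3 fell with 1 array left out. PS2, a phosphatase, rose by 1.21 (SE 0.19) and SQD2, of sulfolipid synthesis, fell by 0.46 (SE 0.09) (1 rose and 1 fell when adjusted over the list alone).

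The hormone lists named in the series title were not called in shoots. Of 24 auxin response genes, 5 rose, 7 fell and 12 did not pass (5 and 9 when adjusted over the list alone; adjusted p = 0.479), and 3 to 7 fell with 1 array left out. IAA20, an Aux/IAA protein, rose 7.78-fold (log2 2.96, SE 0.10), GH3.3, an auxin-conjugating enzyme, rose by 0.77 (SE 0.13), IAA17 fell by 0.90 (SE 0.11) and SAUR23 had the largest fall (log2 -1.04, SE 0.24, adjusted p = 0.019). The SAUR23 call was lost without rml1 replicate 1 (adjusted p = 0.0593), rml1 replicate 3 (0.0595) or wild type replicate 2 (0.0535). The median of this list was -0.23 and camera gave the direction as down, while fry gave it as up. Of 26 genes of auxin synthesis and transport, 9 rose, 5 fell and 12 did not pass (11 and 6 when adjusted over the list alone; adjusted p = 0.238, and 0.00443 with fry), and 2 to 4 fell with 1 array left out. ABCB4, an auxin transporter, rose 6.64-fold (log2 2.73, SE 0.14), TAA1, an enzyme of auxin synthesis, rose by 0.84 (SE 0.12), its relative TAR2 fell by 0.61 (SE 0.08) and PIN5, an auxin carrier of the endoplasmic reticulum, fell by 1.01 (SE 0.12).

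Of 20 genes of strigolactone and karrikin synthesis and signalling, 4 rose, 2 fell and 14 did not pass (6 and 5 when adjusted over the list alone; adjusted p = 0.821). With 1 array left out, 2 to 4 rose and 1 to 2 fell. LBO1, a late enzyme of strigolactone synthesis, rose by 1.42 (SE 0.21), MAX1, a cytochrome P450 of that pathway, rose by 0.93 (SE 0.12), and D27, the isomerase that starts it, fell by 1.41 (SE 0.14). The cleavage enzymes CCD7 and CCD8 did not pass (log2 -0.23, SE 0.11, and -0.13, SE 0.11). Of 22 genes of cytokinin response and turnover, 8 fell and 14 did not pass (11 when adjusted over the list alone; adjusted p = 0.000171, and adjusted p = 0.227 with an estimated correlation). ARR6 fell by 1.67 (SE 0.16), ARR5 fell by 1.47 (SE 0.16), ARR4 fell by 1.38 (SE 0.14) and ARR7 fell by 1.04 (SE 0.17), all of them type-A response regulators.

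The lists of defence hormones were not called. Of 20 salicylic acid and camalexin genes, 3 rose, 2 fell and 15 did not pass (adjusted p = 0.714, with 1 to 2 falling when 1 array was left out), with PAD3, of camalexin synthesis, up by 0.99 (SE 0.13) and PR5 decreased by 0.93 (SE 0.13). Of 21 jasmonate genes, 4 rose, 3 fell and 14 did not pass (adjusted p = 0.807). JAZ1 rose by 1.16 (SE 0.10) and JAZ9, another repressor of jasmonate signalling, fell by 2.20 (SE 0.18). Adjusted over the list alone, the counts were again 3 and 2 for the salicylic acid list and 4 and 3 for the jasmonate list.

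SMR5, SMR7 and SIM, inhibitors of cyclin-dependent kinases, rose in shoots. Of 14 D-type cyclins and inhibitors of cyclin-dependent kinases, 7 rose, 1 fell and 6 did not pass (7 and 1 when adjusted over the list alone; adjusted p = 0.0104, adjusted p = 0.364 with an estimated correlation and 0.0717 with only loci above the median of expression). With 1 array left out, 4 to 7 members of this list rose. The rises were led by SMR5 (log2 2.04, SE 0.14), SMR7 (log2 1.77, SE 0.18) and SIM (log2 1.26, SE 0.14). CYCD6;1 had the only fall (log2 -0.53, SE 0.13, adjusted p = 0.0264), a call lost without any of 4 arrays (adjusted p 0.0558 to 0.082 without rml1 replicate 1, rml1 replicate 2, wild type replicate 2 or wild type replicate 3). Among 20 mitotic genes, 1 rose, 1 fell and 18 did not pass (adjusted p = 0.714), and 1 to 2 fell with 1 array left out. CYCB1;1 rose by 0.46 (SE 0.12, adjusted p = 0.0343), and its call was lost without each array other than rml1 replicate 1 (adjusted p 0.0549 to 0.109) and under quantile normalization of the shoot arrays (0.0605) or array weights (0.0502). CYCA2;4 fell by 0.50 (SE 0.10). Of 13 S-phase genes, 1 rose, 3 fell and 9 did not pass (adjusted p = 0.0848). With 1 array left out, 0 to 4 fell with limma (6 had an unadjusted p under 0.05 with all arrays), and the list was called without wild type replicate 1 (adjusted p = 0.0455), with quantile normalization of the shoot arrays (0.0487) and with fry (0.0454). TSO2, a subunit of ribonucleotide reductase, rose by 0.58 (SE 0.10), and MCM7, of the replicative helicase, had a log2 fold change of -0.46 (SE 0.13, adjusted p = 0.0388), lost without each array other than rml1 replicate 2 and wild type replicate 1 (adjusted p 0.102 to 0.126). Adjusted over the list alone, 1 mitotic gene fell, and 1 S-phase gene rose and 4 fell.

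The nuclear photosynthesis genes were called down (adjusted p = 0.00523, and adjusted p = 0.586 with an estimated correlation) with a median of -0.09. Of 33 members, 6 fell and 27 did not pass (5 when adjusted over the list alone). With the trend and robust options of eBayes 10 fell, and with 1 array left out 4 to 5 fell. The largest fall was that of PRK, phosphoribulokinase (log2 -0.62, SE 0.09). The seed storage and seedling establishment list was not called (adjusted p = 0.714, 0.00348 with only loci above the median of expression and 0.0202 with fry): its median was -0.12 and its mean 0.77. ICL, MLS and PCK1, the last a phosphoenolpyruvate carboxykinase (log2 2.58, SE 0.21), rose, CRC, a seed storage protein, had a log2 fold change of -0.45 (SE 0.11, adjusted p = 0.0244) and 11 members did not pass. The CRC call was lost without rml1 replicate 1 (adjusted p = 0.087), rml1 replicate 3 (0.0676), wild type replicate 2 (0.0642) or wild type replicate 3 (0.0676). No member of the 11 heat shock genes passed with limma, and 0 had an unadjusted p under 0.05 (adjusted p of the list = 0.45). Adjusted over the list alone, 3 members of the seed list rose and 2 fell.

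Lists of root cell types were not called in shoots with all arrays. Among 9 endodermis genes 2 rose and 7 did not pass (adjusted p = 0.0609, and a call at 0.00764 without rml1 replicate 1; 1 to 4 rose with 1 array left out), among 10 root hair genes 2 fell and 8 did not pass (adjusted p = 0.461, with 1 to 2 falling when 1 array was left out), and among 12 root meristem regulators 1 rose and 11 did not pass (adjusted p = 0.714). PER64, a peroxidase of the Casparian strip, rose by 0.90 (SE 0.16) and GL2, a repressor of root hair fate, fell by 0.58 (SE 0.11). SHR, a regulator of the stem-cell niche, had a log2 fold change of 0.44 (SE 0.12, adjusted p = 0.0335), lost without each array other than wild type replicate 3 (adjusted p 0.0681 to 0.107) and under quantile normalization of the shoot arrays (0.0825). Adjusted over the list alone, 3 endodermis genes rose, 2 root hair genes fell and 0 root meristem regulators passed with limma, 2 of the latter having an unadjusted p under 0.05.

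**Figure D2:**
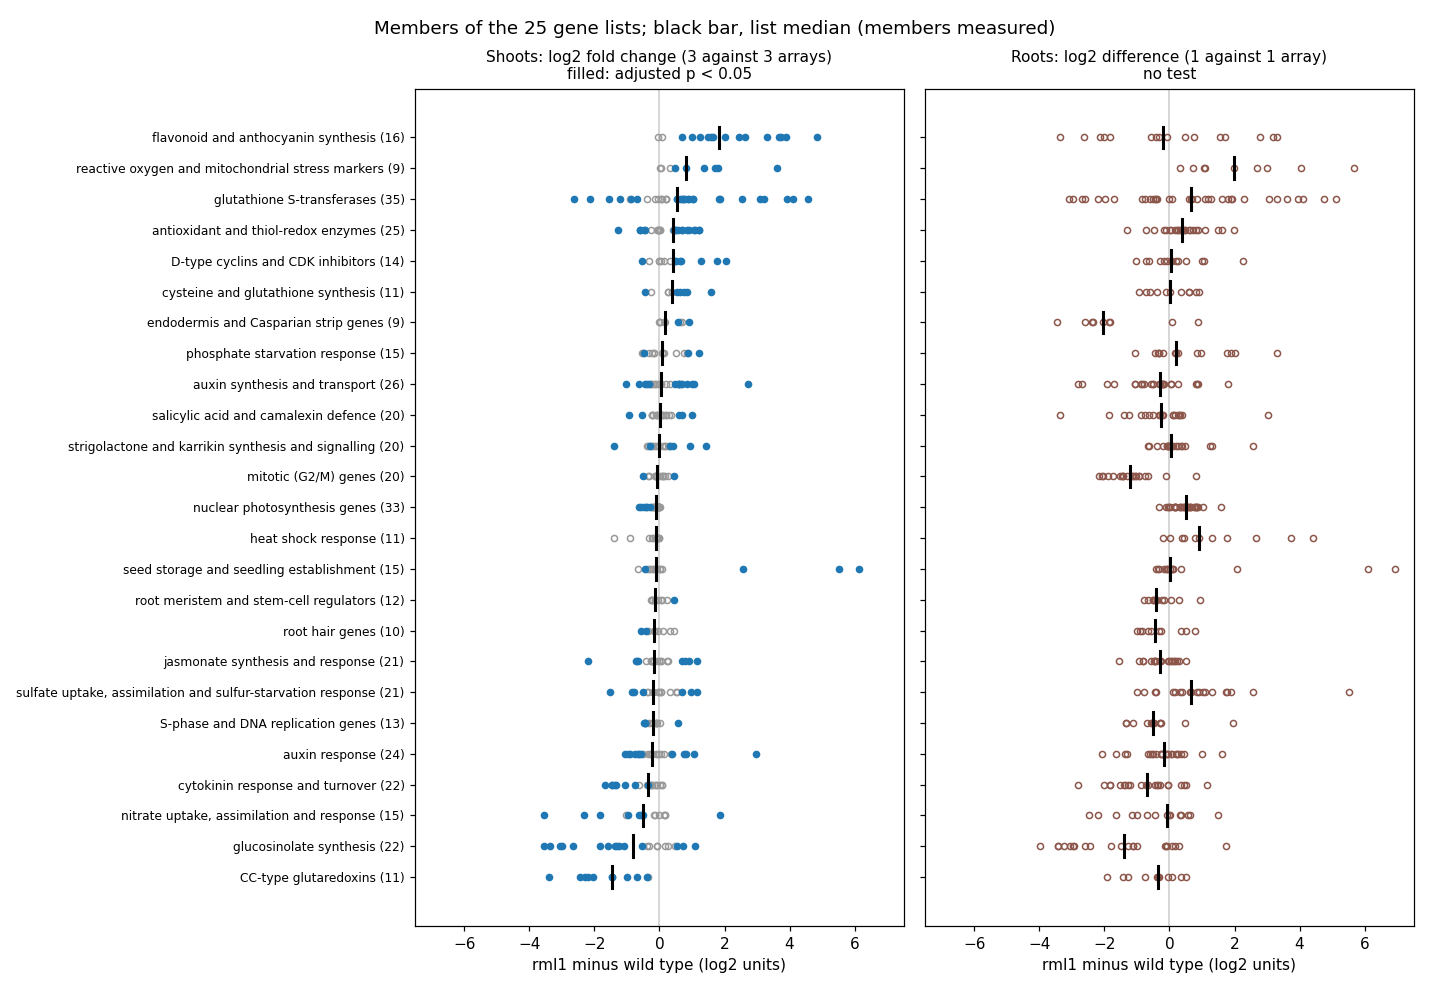
Log2 difference (rml1 minus wild type) of each member of the 25 gene lists, in shoots (means of 3 arrays each) and in roots (1 array each), 1 point per gene, filled where the adjusted p in shoots was under 0.05, with a black bar at the list median. Flavonoid genes had a median of 1.82 in shoots and -0.20 in roots, CC-type glutaredoxins -1.47 and -0.35, and mitotic genes -0.08 and -1.22.

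The second comparison set the rml1 root array against the wild type root array. With 1 array per genotype there is no test, and values describe these arrays alone. GSH1 was at 8.97 in the rml1 root and 8.14 in the wild type root, a difference of 0.83. The glyoxylate cycle genes ICL (123-fold, log2 6.94) and MLS (68.9-fold, log2 6.11) were among the 10 largest positive differences, as were DOGT1, a glucosyltransferase (83.2-fold), DIN2, a beta-glucosidase induced in the dark (73.1-fold), and AT2G21640 (51.4-fold). The others were AT5G24640 (67.1-fold), AT4G12735 (62.7-fold), AT2G18150 (61.2-fold), AT5G52390 (51.4-fold) and AT2G04050 (46.9-fold). The largest negative difference was that of MLP328, a latex protein homologue, 61.9-fold higher in the wild type root, followed by AT3G59370 (45.3-fold), AT3G18450 (37.8-fold), ANNAT7, an annexin (31.0-fold), AT5G03995 (29.1-fold) and AGP13, an arabinogalactan protein (28.6-fold). AT1G12080 (28.4-fold), AT4G11210 (27.4-fold), AT4G11320 (25.3-fold) and AT3G26460 (25.3-fold) completed the set. Among 16075 loci with at least 1 root array above its median, 1414 were at least 2-fold higher and 1946 at least 2-fold lower in the rml1 root. By comparison, 75 to 168 of these loci were 2-fold apart between 2 shoot replicates of a genotype. The spread between shoot arrays need not hold for root arrays, and these loci were selected on their root levels.

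Mitotic, endodermis, cytokinin and glucosinolate genes were lower in the rml1 root. The median difference of 20 mitotic genes was -1.22, below all 10000 random lists of matched expression, with KNOLLE, a cytokinesis syntaxin, at -2.17 and CYCB1;1 at 0.82. S-phase genes had a median of -0.51 (percentile 0.98 among random lists), PCNA1 being lowest at -1.35 and RNR2A highest at 1.95. Endodermis genes had a median of -2.04, below all random lists, with CASP5, of the Casparian strip, at -3.46. Cytokinin genes had a median of -0.69 (percentile 0.01), ARR7 being lowest at -2.82 and CKX5, a cytokinin oxidase, highest at 1.15. Glucosinolate genes had a median of -1.39, below all random lists, with BCAT4 at -3.97 and MYB51 at 1.73. The root meristem list had a median of -0.40 (percentile 1.29), the root hair list -0.44 (3.41) and the CC-type glutaredoxins -0.35 (3.39), with ROXY2 at -1.91.

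Markers of reactive oxygen and mitochondrial stress had a median of 1.99, with 9 of 9 members above 0, and glutathione S-transferases a median of 0.66, both above all random lists. GSTF6 differed by 5.11 and GSTU26 by -3.09. Heat shock genes had a median of 0.92 (percentile 99.99), HSP17.6A being highest at 4.40. HSP17.6A also varied among shoot replicates (SD 0.82 in rml1 and 1.08 in the wild type). Heat shock genes moved together in shoots (estimated correlation 0.41), so 1 root array alone can make such a percentile extreme. The sulfate list had a median of 0.67 (percentile 99.99), with BGLU28 at 5.51 and APS3, an ATP sulfurylase, at -1.01. Photosynthesis genes had a median of 0.51 (percentile 99.95), with RBCS1A, a Rubisco subunit, at 1.60. Antioxidant enzymes had a median of 0.40 (percentile 99.8), with CAT3 at 1.99 and FSD1, a superoxide dismutase, at -1.30.

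Auxin synthesis and transport genes had a root median of -0.29 (percentile 1.39), with TAR2 at -2.80, PIN5 at -2.69 and ABCB4 at 1.81. Auxin response genes had a median of -0.16 (percentile 9.08), from IAA3 at -2.09 to GH3.3 at 1.62. The strigolactone list had a median of 0.05 (percentile 65.6), with CCD8 at 2.58. Medians of the jasmonate list (-0.29, percentile 1.40, MYC2 at -1.55) and of the salicylic acid list (-0.26, percentile 2.80) lay low, although PAD3 differed by 3.03 and WRKY54, a transcription factor, by -3.38. Flavonoid genes had a median of -0.20 (percentile 10.9), with DFR at 3.29 and FLS1, flavonol synthase, at -3.36. The remaining medians were 0.21 for phosphate starvation (percentile 89.5, RNS1, a ribonuclease, at 3.30), 0.06 for D-type cyclins and inhibitors (50.6, SMR7 at 2.26), 0.02 for cysteine and glutathione synthesis (49.3), 0.02 for the seed list (70.8) and -0.08 for the nitrate list (38.5, NIA2, a nitrate reductase, at 1.48 and BT1 at -2.47).

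The third comparison asked whether the loci changed in shoots differ in the same direction between the root arrays. ICL, MLS, GPT2, TH8 (root 5.25) and MYB75 (root 2.80) were higher in rml1 in both organs, and AT3G01345 (root -4.65), SWEET16 (root -3.57) and CYP83A1 (root -3.44) were lower in both. GPT2 and MYB75 were lower in the rml1 root (6.64 and 5.52) than in rml1 shoots (means 10.59 and 8.71). Shoot tissue in the rml1 root sample could therefore add to their root differences, which was not tested. ICL, MLS and TH8 were higher in the rml1 root than in rml1 shoots. AT1G66100, the largest fall in shoots, differed by -0.68 in roots, and PPT2 by -0.31. Of the 7138 loci changed in shoots, 5032 (70.5%, exact binomial 95% interval 69.4 to 71.6) had the same sign in roots: 73.8% of those that rose and 66.3% of those that fell. Over all loci, 51.3% lay below 0 in roots. Across the changed loci Pearson's r of the differences was 0.50 and Spearman's rho 0.47, and across all loci 0.36 and 0.32. Loci are not independent replicates, and roots and shoots may come from the same seedlings, so these values and the interval are descriptions. At least 2-fold differences in both organs had the same direction at 323 higher and 212 lower loci, and opposite directions at 36 loci higher in shoots and 24 lower in shoots.

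**Figure D3:**
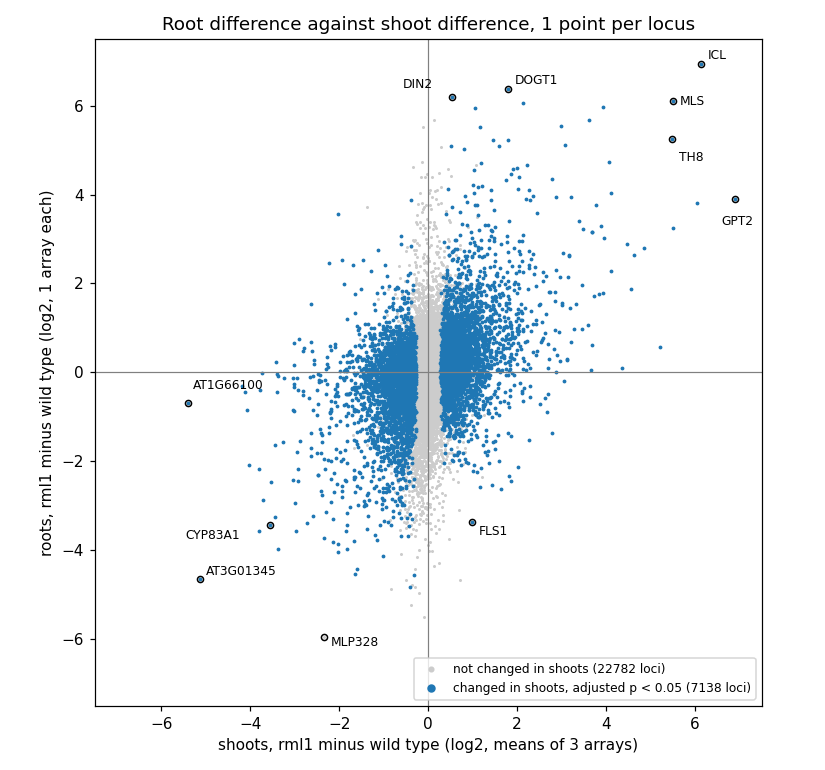
Root difference (1 array per genotype, vertical axis) against shoot difference (means of 3 arrays per genotype, horizontal axis), log2 rml1 minus wild type, 1 point per locus. Blue points are the 7138 loci changed in shoots, of which 70.5% had the same sign in roots. Named points include ICL and MLS, far up in both organs, and AT3G01345, far down in both.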

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

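The tests of root tissue in the shoot samples and of a shared response in this part were chosen only after the result they bear on was seen, and the other tests were set before their values were looked at. Among named genes called in shoots, 7 had a root difference of at least 1 log2 unit in the opposite direction. The difference between organs was not tested, because the roots have 1 array per genotype. SULTR2;1, a sulfate transporter of vascular tissue, fell by 1.51 in rml1 shoots and was higher by 1.88 in the rml1 root. PER64, a peroxidase of the Casparian strip, rose by 0.90 in shoots and differed by -2.04 in roots. MYC2, a regulator of jasmonate signalling, rose by 0.69 in shoots and differed by -1.55 in roots. FLS1, flavonol synthase, had a shoot log2 fold change of 0.99, a call lost without rml1 replicate 1 (adjusted p = 0.0913), rml1 replicate 3 (0.101), wild type replicate 1 (0.0591) or wild type replicate 2 (0.0626), and differed by -3.36 in roots. CHS, chalcone synthase, rose by 1.63 in shoots and differed by -2.62 in roots, and ASN1, an asparagine synthetase, fell by 2.63 in shoots and was higher by 1.54 in the rml1 root. APR2, an enzyme of sulfate reduction, had a shoot log2 fold change of -0.52 (adjusted p = 0.0202), a call lost without rml1 replicate 1 (0.0671) or rml1 replicate 3 (0.0725), and differed by 1.30 in roots.

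The rml1 shoot arrays correlated more closely with the root arrays than the wild type shoot arrays did, by 0.0384 with the rml1 root and 0.0149 with the wild type root on average. Root tissue left on the shoots would raise the 100 loci that were at least 4 log2 units higher in both root arrays than in wild type shoots. Their median shoot change was 0.0803 (95% bootstrap interval over loci -0.04 to 0.15, which does not cover the spread of arrays). Of these loci 14 rose and 7 fell, beside 13.3% and 10.6% of all loci, which argues against root tissue as the whole cause. The gain with the rml1 root exceeded that with the wild type root by 0.0236 (0.0201 to 0.0276 over the 3 arrays), in line with a response of the mutant shared by both organs. A small admixture of rml1 root with its own expression could add to that gain and stays open. Shoot tissue in the rml1 root sample could also add to it, was not tested and stays open. The wild type shoot arrays, too, correlated more with the rml1 root (0.8495 to 0.8578) than with the wild type root (0.8405 to 0.8511). Photosynthesis genes had a higher median in the rml1 root (7.99) than in the wild type root (7.49). No harvest time is given, so a harvest difference shared by both organs cannot be told apart from a response of the mutant.

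GPT2 and anthocyanin genes rose in rml1 shoots, while BT5 and nitrate-linked regulators fell. A candidate explanation is a surplus of sugar in the shoots. The median of 11 genes known to be repressed by sugar was -0.89, with 7 falling, as that explanation would predict. The 4 that did not pass lay above 0 (0.18 to 0.72), so the list was not uniform. The list was limited to genes not seen before this test. ICL and MLS, already seen to rise by 6.13 and 5.50, could therefore not enter it. Whether a sugar surplus allows such rises was not tested, so the explanation stays open. Of 5 sugar-induced genes, 4 rose (median 1.13), among them APL3, of starch synthesis, by 3.16. Another time of day at harvest cannot be told apart from the genotype: the means of morning and evening clock genes differed by -0.51, between the bounds set for a clear answer, with CCA1, a morning gene, decreased by 0.76. The medium of both genotypes held 0.5% sucrose, its uptake and sugar in the shoots were not measured, and no harvest time was given.

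AT3G01345 was lower in all rml1 arrays in both organs, with differences of -5.14 in shoots and -4.65 in roots. If the mutant line carried a changed stretch of genome, other loci with such differences might lie near each other. Among 24 loci at least 8-fold apart in the same direction in both organs, 0 pairs lay within 20 loci. A locus low in both root arrays could not enter this set. The loci on either side, AT3G01340 and AT3G01350, differed by 0.08 and -0.01 in shoots, and PPT2, another of the largest falls in shoots, lies 24 loci away. Of 40 neighbours within 20 loci, 10 were called in shoots (4 higher and 6 lower), beside 23.9% of all loci, and among them DOX1, 8 loci away, differed by -2.22 in shoots (adjusted p 0.0622 to 0.0715 without rml1 replicate 2 or wild type replicate 2 or 3) and 0.59 in roots, and AT3G01260, 20 loci away, by -1.19 (adjusted p 0.0777 to 0.141 without any array other than wild type replicate 1, and 0.0665 with quantile normalization) and -3.67. The count of 0 pairs cannot exclude a changed stretch, because a stretch with only 1 such locus would also give 0. A changed stretch, a change limited to the locus itself and a true difference of expression all stay open.

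The real grouping of the 6 shoot arrays gave 7138 changed loci, and the highest of the other splits into 3 and 3 gave 0. This was 1 of 10 splits, too few for a share under 0.05. In the other splits each group held arrays of both genotypes, so genotype differences added to the spread within groups. Low counts there were therefore likely in advance.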

How the results depend on the processing

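The test of each table entry by itself (7221 loci) was chosen after the data were seen, and the other alternatives before. Leaving out 1 shoot array, so that fewer samples were fitted, gave 4508 to 6480 changed loci. Of these, 2526 to 3549 were higher and 1982 to 2931 lower, with the fewest without rml1 replicate 3. That sample pooled 108 shoots, the most of the rml1 shoot samples. Why its removal gave the fewest calls was not tested. The other normalizations, filters, variance models and weights gave 6933 to 7850, and the higher share of calls moved from 55.6% to 51.2% with quantile normalization and to 60.6% with the filter at the median. An adjusted p under 0.01 left 3583 loci and a minimum of 2-fold left 1446. Of the 10 called lists, 0 were called with an estimated correlation. The estimates ran from -0.051 to 0.46 over the lists, beside the preset 0.01, and the flavonoid list had 0.46. The nitrate list, at -0.051, also lost its call (camera unadjusted p 0.053, against 0.0109 with the preset). A correlation above the preset was therefore not the only cause, and other causes were not tested. With the filter at the median, the cysteine and glutathione (adjusted p = 0.0933), transferase (0.0708) and D-type cyclin (0.0717) lists were not called and the seed list was (0.00348); the cause was not tested. With the replicate block, 5189 loci were called. Deviations of same-numbered arrays did not correlate (r -0.035, -0.0027 and -0.098). These few correlations of normalized values cannot exclude shared harvests or batches, so whether the numbers pair the samples stays unknown. With the block, GSH1, GSTF14, MCM7, SHR and AT3G01260 lost their calls (limma adjusted p 0.0504, 0.0584, 0.0581, 0.0833 and 0.0599). Of 58 loci named by the rule, 9 lost their call without some array and 0 changed direction; of 64 further loci examined, 11 lost it under some setting. In roots, 632 loci were higher and 801 lower above the 75th percentile of expression, 3274 and 3311 at 1.5-fold, and 371 and 499 at 4-fold, as the thresholds imply. All list medians in roots, and the 53 loci named by the rule for roots, kept their sign under quantile normalization and centring. The share of loci with the same sign in roots was 76.5% and r was 0.588 for loci changed at least 2-fold in shoots, and the share ran from 70.04% to 72.16% without 1 array.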

Other observations

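The tests in this part were set before their own values were looked at, but the loci named in the first paragraph were chosen after their values were seen. At 24 loci, rml1 and wild type differed at least 8-fold in the same direction in shoots and between the root arrays, 19 higher and 5 lower in rml1. Besides GPT2, ICL, MLS and TH8, the higher loci included GSTF6 (shoot 3.08, root 5.11), UGT74E2, a glucosyltransferase of indole-butyric acid (3.77 in both organs), NIT2, a nitrilase (3.69 and 3.16), DFR (3.89 and 3.29) and MYB90 (3.69 and 3.17). Less described loci of this kind were AT2G18193 (4.11 and 4.04), AT5G09570 (4.06 and 4.73) and AT4G12735 (3.93 and 5.97). Lower in both organs were AT3G01345, SWEET16, BCAT4 (-3.37 and -3.97), CYP83A1 (-3.55 and -3.44) and QQS, a regulator of starch content (-3.44 and -3.25). In shoots each of the 24 loci had an adjusted p of 0.00146 or lower with limma (n = 3 arrays each), and the root values have no test.

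Sugar-linked genes added detail on carbon use. ASN1 and DIN10, both repressed by sugar, fell by 2.63 each in shoots, and SUS3, a sucrose synthase, rose by 1.13. In roots the median of 5 sugar-induced genes was 1.90, with 5 of 5 above 0, and that of 11 sugar-repressed genes was 0.03. Of 2 morning clock genes 1 fell, and of 5 evening clock genes 1 rose and 4 did not pass.

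SMR5, SMR7 and CYCB1;1, genes known to respond to DNA damage, were higher in rml1 shoots, while CYCA2;4 fell and the other mitotic genes did not pass. The CYCB1;1 call was lost without each array other than rml1 replicate 1 (limma adjusted p 0.0549 to 0.109). Among 9 other genes of that response the median shoot change was 0.48, with 6 rising and 3 not passing, which lies between the bounds set in advance and leaves the question open. XRI1 rose by 1.63 (SE 0.15), PARP2 by 1.37 (SE 0.10), GMI1 by 1.03 (SE 0.10) and TRFL10 by 0.94 (SE 0.10), and between the root arrays 9 of 9 were above 0 (median 0.94).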
